A study of Homo sapiens with 9 samples.

How the data were processed

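RNA sequencing counts of 9 libraries from human K-562 cells with a B2M tdTomato genotype were analysed, 3 libraries in each of 3 groups: mock-treated cells, cells given the tripartite ETR with a full-length gRNA, and cells given the same ETR with a gRNA of 16 nt. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, cells were grown in RPMI-1640 medium, ETR mRNA and gRNA were delivered by nucleofection, total RNA was extracted with the RNeasy Mini Kit, and libraries were made with the NEBNext Ultra RNA kit. The authors deposited 1 table of raw read counts per gene, without normalization. Per the submitters' processing notes, the tools were bcl2fastq 2.20, FastQC 0.11.9, Trim Galore 0.6.6, STAR 2.7.6a, featureCounts, Subread 2.0.1 and DESeq2 1.30.0, with the genome build GRCh38. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Counts of overlapping or oppositely oriented genes, of near-identical gene copies and of genes with many processed pseudogenes are therefore uncertain. The table held 59653 gene symbols, of which 33525 had a count in at least 1 library and 74 were annotated on several chromosomes. It held 0 sample columns without a label. Gene coordinates are those of the deposited table.

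Total counts ranged from 23763529 to 33260228 per library. Before averaging, the 9 pairs of libraries within a group were compared. Their chi-square per degree of freedom, over genes with a mean count of at least 10, ranged from 12.0 to 31.0 and the correlation of their log2 CPM from 0.989 to 0.994. No pair agreed within sampling noise, and 5 of the 27 pairs across groups had a lower chi-square than any pair within a group, so each library counted as 1 replicate. CPM values were computed here from the deposited counts with TMM-scaled library sizes.

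The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with TMM scaling, the filterByExpr filter by group (minimum count 10) and 1 fit of all 9 libraries with a term per group and no replicate block. It left 15213 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Each gRNA group was compared with mock and the gRNA groups with each other. A further fit compared the 6 ETR libraries with the 3 mock libraries. For B2M alone, log2 CPM values were compared with exact two-sided permutation tests in scipy 1.17.1 under Python 3.11.15.

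Gene lists were tested with camera in limma 3.58.1 on TMM log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01. Benjamini-Hochberg adjustment covered the 21 of 23 lists with at least 5 measured members. Camera with an estimated correlation and the directional fry test, which asks whether a list's genes move one way without comparing them with other genes, were run beside it. Of 636 list entries, 1 (NESP55) was not found in the table. Genes whose annotated span lay within 1 Mb of B2M formed a further list, adjusted over all genes and over the list alone.

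The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took B2M, the called genes with the largest changes, up to 4 members of each list with the smallest p in each comparison, and the genes within 1 Mb of B2M. After the values were seen, this was narrowed by a fixed order, to 4 members with the smallest p for each called list, 1 for each other list and the 2 neighbours of B2M with the smallest p. The results of some genes that this order took are not reported here. Genes named outside this rule were chosen after their values were seen.

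The scripts were tested on simulated counts drawn from the real means and library sizes, with 200 changed genes. With full-length gRNA against mock, 76.1% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold were called among 15017 tested genes, along with 15 unchanged genes. With 16-nt gRNA against mock the shares were 68.7%, 95.5% and 100% among 15056 tested genes, along with 8 unchanged genes. With 16-nt against full-length gRNA they were 77.6%, 94.0% and 100% among 15015 tested genes, along with 15 unchanged genes. With 200 genes changed at once the adjusted threshold is easier to reach than with 1 changed gene. Counts were also drawn gene by gene, without the variation that genes of a real library share. These shares therefore do not give the power to call a single changed gene in the real data. A list shifted by 0.3 on the log2 scale was recovered in each of these comparisons and 0 unchanged lists were called by camera. These lists held random genes drawn independently, while estimated correlations in the real lists reached 0.786 (mitochondrially encoded genes). The simulation therefore cannot show how often camera calls an unchanged real list. The shift was also larger than the medians of the lists called in the real data.

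The replicate numbers come from the sample titles, which do not say what a number shares. Deviations from the group means in the 16-nt and full-length gRNA libraries correlated at 0.361, 0.196 and 0.572 for replicates 1, 2 and 3, all above the bound of 0.1 set for pairing, so the numbers pair these groups. The bound was not met by every pair against mock.

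Alternatives were DESeq2 size factors within edgeR, library totals alone, no filter on low counts, a filter of 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test of all 33525 genes with a count, the replicate number as a block, fits of the compared groups alone, stricter thresholds, and each library left out in turn. Fits without both ETR replicate 3 libraries, and gene lists scaled by library totals alone, were added after seeing the data. The tdTomato transcript, gRNA target positions and off-target sites were not analysed here.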

Results

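K-562 is a human chronic myeloid leukaemia line that grows in suspension and transcribes erythroid and megakaryocytic genes. The cells carried a B2M tdTomato genotype, tdTomato being a red fluorescent protein. B2M encodes beta-2-microglobulin, the invariant light chain that MHC class I molecules need to reach the cell surface. Cells were mock-treated or nucleofected with mRNA for a tripartite ETR, a fusion protein built on dCas9, and a gRNA directed at the B2M promoter. dCas9 is a Cas9 protein without nuclease activity that binds DNA where its gRNA leads it. The gRNA was either full length or shortened to 16 nt, and 3 libraries were sequenced per group. Total counts were 25436995, 33260228 and 26471128 in mock replicates 1 to 3, 28812940, 28337890 and 23763529 with the full-length gRNA, and 25377704, 30730369 and 25818945 with the 16-nt gRNA. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. They also do not say what the mock treatment contained, how long after nucleofection RNA was taken or whether cells were sorted. The library names in the labels call the mock libraries UT, which is not explained. If mock cells were not nucleofected, effects of nucleofection and of the ETR cannot be told apart in comparisons with mock.

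B2M lies on the plus strand of chromosome 15 at positions 44711487 to 44721256 of GRCh38. In the mock libraries its counts were 3681, 4304 and 3718. They were 309, 268 and 216 with the full-length gRNA and 462, 714 and 423 with the 16-nt gRNA. Scaled to depth, B2M stood at 139 ± 7.11 CPM in mock cells, 9.71 ± 0.977 CPM with the full-length gRNA and 19.2 ± 2.96 CPM with the 16-nt gRNA (SD, n = 3 each). These levels were 6.98% ± 0.702 and 13.8% ± 2.13 of the mock mean (SD, n = 3 each). As means over all cells of a library, they do not separate a lower level per cell from a share of cells that kept B2M. B2M in each library thus went with its label. The 3 groups did not overlap, and an exact two-sided permutation test of log2 CPM gave p = 0.10 for each pair of groups, the smallest p that 3 against 3 libraries allow.

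**Figure D1:**
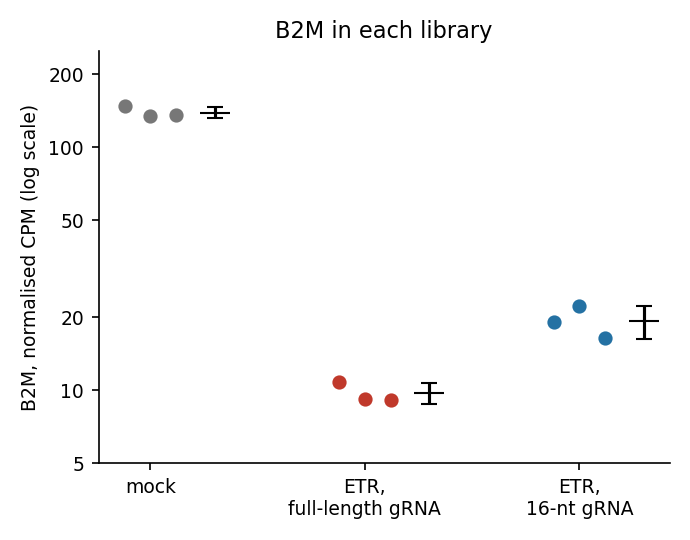
B2M level in each of the 9 libraries (CPM, log axis), by group, each point being 1 library with the group mean and SD drawn beside it. The mock libraries lie at 135 to 147 CPM, those with the full-length gRNA at 9.09 to 10.8 CPM and those with the 16-nt gRNA at 16.4 to 22.3 CPM.

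The ETR libraries of replicate 3 stood apart from the rest. On the first principal component, which held 33.1% of the variance, they lay at 30.7 with the full-length gRNA and 26.9 with the 16-nt gRNA, while the other 7 libraries lay between -19.1 and 6.84. RN7SL1, the RNA of the signal recognition particle, took 6.66% and 5.95% of their counts and 3.36% to 5.56% in the other 7 libraries. Mitochondrially encoded genes took 0.233% and 0.251% of their counts and 0.163% to 0.352% in the others. By chi-square of count pairs, 9 of the 9 libraries were nearest to a library of another group. The closest pairs were full-length with 16-nt gRNA replicate 3 (chi-square per degree of freedom 3.00), mock replicate 2 with 16-nt gRNA replicate 1 (3.26) and mock with full-length gRNA replicate 1 (4.56).

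The first comparison asked which transcripts differed between cells given the ETR with the full-length gRNA and mock-treated cells. B2M fell 14.3-fold, a log2 fold change of -3.84 (SE 0.12, 95% CI -4.09 to -3.59, edgeR adjusted p = 3.50e-11). Among the gene lists, heat shock proteins, which help other proteins fold, fell together, with 14 of 18 measured members lower. Lists of hypoxia and glycolysis genes (25 of 31 lower) and of G1/S and replication genes (20 of 28 lower) also fell, and cytosolic ribosomal proteins rose (53 of 74 higher). These 4 list calls rested on small shifts, with median log2 fold changes of -0.11, -0.047, -0.056 and 0.040, and 0 of the lists passed with an estimated correlation.

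B2M was the only one of 15213 tested genes called by edgeR with the full-length gRNA, and the only one called by DESeq2, which tested all 33525 genes with a count, so that 0 genes rose and 1 fell. At an unadjusted p under 0.05, edgeR gave 435 genes, or 2.86% of those it tested, and DESeq2 gave 354 of its larger set. The edgeR share lies under the 5% that chance alone would give, which points to a conservative test. Few calls therefore do not show that few genes differed. The next lowest edgeR adjusted p was 0.992, and without a filter on low counts 6 genes were called. Of 11704 genes with a mean log2 CPM of at least 1, 99.0% had a 95% confidence interval that lay within 2-fold in either direction and 90.9% within 1.5-fold. SCNN1D, a subunit of the epithelial sodium channel, chosen after its values were seen, had the largest positive log2 fold change among these, 0.94 (SE 0.38, edgeR adjusted p = 0.992). Its counts were 31, 32 and 47 in mock libraries, 49, 76 and 78 with the full-length gRNA and 26, 85 and 100 with the 16-nt gRNA. With the first principal component as a covariate, its value for the 6 ETR libraries together went from 0.95 (SE 0.32) to 0.46 (SE 0.23).

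**Figure D2:**
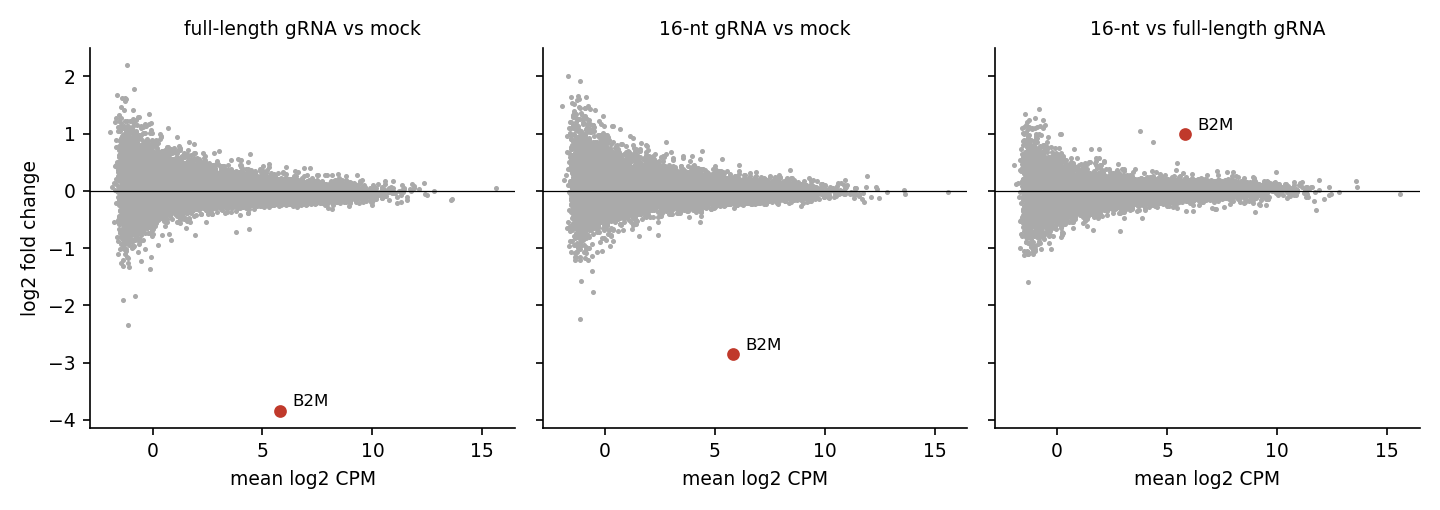
Log2 fold change of each tested gene against its mean log2 CPM in the 3 comparisons between groups, each point being 1 gene and the called gene marked. B2M stands at -3.84 with the full-length gRNA and -2.85 with the 16-nt gRNA against mock, and at 0.99 between the gRNAs.

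The heat shock list fell with a camera adjusted p = 0.00691, and with adjusted p = 0.412 with an estimated correlation. HSPH1, a co-chaperone of HSP70, went from 86.7 ± 1.28 to 74.1 ± 8.14 CPM (SD, n = 3 each), a log2 fold change of -0.23 (SE 0.09). DNAJA1, HSPD1 and HSP90AA1, which encode an HSP40 co-chaperone, the mitochondrial HSP60 and a cytosolic HSP90, had log2 fold changes of -0.24, -0.22 and -0.20. Without full-length gRNA replicate 3 alone HSPH1 stood at -0.14, DNAJA1 at -0.16 and HSP90AA1 at -0.067, and without full-length gRNA replicate 2 HSP90AA1 stood at -0.30. Without both ETR replicate 3 libraries the heat shock list had an adjusted p = 0.00386, and without mock replicate 2 it had 0.101.

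Hypoxia and glycolysis genes fell with a camera adjusted p = 0.0327, and with adjusted p = 0.802 with an estimated correlation. NDRG1, a hypoxia-induced gene, went from 105 ± 7.21 to 86.1 ± 4.12 CPM (SD, n = 3 each), a log2 fold change of -0.28 (SE 0.08). Carbonic anhydrase CA9, the neuronal enolase ENO2 and lactate dehydrogenase LDHA had log2 fold changes of -0.31, -0.15 and -0.20. CA9 stood at -0.12 without mock replicate 2 and -0.47 without mock replicate 3, and ENO2 at -0.23 without full-length gRNA replicate 2. LDHA stood at -0.34 without full-length gRNA replicate 1 and -0.13 without full-length gRNA replicate 3. The G1/S and replication list fell with a camera adjusted p = 0.0318, and with adjusted p = 0.802 with an estimated correlation. Its members GINS1, POLA1, RRM2 and CLSPN, which act in replication origin firing, primer synthesis, deoxynucleotide supply and fork signalling, had log2 fold changes of -0.19, -0.16, -0.15 and -0.16. CLSPN stood at -0.27 without full-length gRNA replicate 1 and -0.030 without full-length gRNA replicate 3. The ribosomal protein list rose with a camera adjusted p = 0.0327, and with adjusted p = 0.802 with an estimated correlation. Log2 fold changes were 0.39 for RPS29, 0.35 for RPS27, 0.28 for RPS21 and 0.26 for RPS7, all uncertain because ribosomal protein genes have many processed pseudogenes. RPS29 stood at 0.23 without mock replicate 3, and RPS21 and RPS7 at 0.18 and 0.16 without full-length gRNA replicate 3. RPS27 stood at 0.54 without full-length gRNA replicate 1 and 0.16 without full-length gRNA replicate 2. Without both ETR replicate 3 libraries these 3 lists had adjusted p values of 0.579, 0.698 and 0.522, in the order given, and without full-length gRNA replicate 3 alone 0.542, 0.711 and 0.542. Without mock replicate 1 each had 0.115. Without mock replicate 2 the hypoxia list had 0.354 and the G1/S list 0.214, and without mock replicate 3 the ribosomal protein list had 0.710. With a filter of 1 CPM in 3 libraries the hypoxia list had 0.0627.

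The other 17 tested lists were not called with the full-length gRNA (camera adjusted p from 0.134 to 0.876). Some were called with 1 library left out. Without mock replicate 3 histones were lower (camera adjusted p = 3.93e-06), and without mock replicate 2 mitochondrially encoded genes were higher (0.000101). MHC class I presentation genes, whose products pair with beta-2-microglobulin or load class I molecules with peptides, had 11 of 18 measured members higher, and the chaperone CANX had a log2 fold change of -0.22 (SE 0.10). The type I interferon list had 8 of 20 higher (EIF2AK2, the RNA-activated kinase PKR, -0.14), NF-kB and inflammatory genes 8 of 15 (NFKBIA, 0.12) and immediate early genes 17 of 20 (MYC, -0.13). p53 targets had 14 of 23 higher, with DDB2, a nucleotide excision repair gene, at 0.22. The integrated stress and unfolded protein response had 12 of 30 higher (VLDLR, -0.23), and mitosis genes 8 of 24 (the spindle motor KIF11, -0.19). Of lineage genes, 18 of 34 erythroid members were higher, with the transferrin receptor TFRC at -0.27, and 1 of 6 megakaryocyte members, with RUNX1 at -0.16. Cholesterol synthesis genes had 14 of 25 higher. TFRC stood at -0.16 without mock replicate 1, and MYC and RUNX1 at -0.057 and -0.096 without mock replicate 2. NFKBIA stood at 0.080 without mock replicate 3, and EIF2AK2, RUNX1 and KIF11 at -0.23, -0.070 and -0.29 without full-length gRNA replicate 1. CANX and VLDLR stood at -0.14 and -0.36 without full-length gRNA replicate 2, and EIF2AK2, MYC, VLDLR, RUNX1 and KIF11 at -0.079, -0.071, -0.15, -0.25 and -0.10 without full-length gRNA replicate 3.

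Lists tied to repression and DNA methylation were also not called. The DNA methylation and KRAB repression machinery had 8 of 24 measured members higher, with CBX3, which encodes a heterochromatin protein, at a log2 fold change of -0.23. Germline genes silenced by DNA methylation had 5 of 18 higher (SYCE1, a synaptonemal complex gene, -0.30) and imprinted genes 7 of 16 (L3MBTL1, 0.78, SE 0.32). Replication-dependent histones had 8 of 22 higher, with H4C5 at -0.31, uncertain because H4 genes are near-identical copies. Mitochondrially encoded genes had 10 of 13 higher, with MT-CO1 at 0.20, and MT-CO1 was at -0.033 without full-length gRNA replicate 2. Among markers of other cells, fibroblast and endothelial genes had 4 of 7 higher (COL6A2, 0.21) and epithelial genes 4 of 10 (CLDN3, -0.53, SE 0.22). Only 2 lymphocyte genes (CD3D, 0.81, SE 0.42) and 3 of monocytes and granulocytes (CSF3R, 0.72, SE 0.44) were measured, too few for a list test. CD3D stood at 0.54 without mock replicate 1, and SYCE1 and MT-CO1 at -0.15 and 0.32 without mock replicate 2. CBX3, MT-CO1 and COL6A2 stood at -0.10, 0.099 and 0.13 without mock replicate 3, and H4C5 and COL6A2 at -0.20 and 0.32 without full-length gRNA replicate 2. MT-CO1 and COL6A2 stood at 0.36 and 0.074 without full-length gRNA replicate 3. Over all lists, edgeR called 0 of 478 members and DESeq2 0, with 14 and 15 at an unadjusted p under 0.05, and adjusted over the list alone 0 were called in each list. Median, mean and test differed in sign for p53 targets and imprinted genes.

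**Figure D3:**
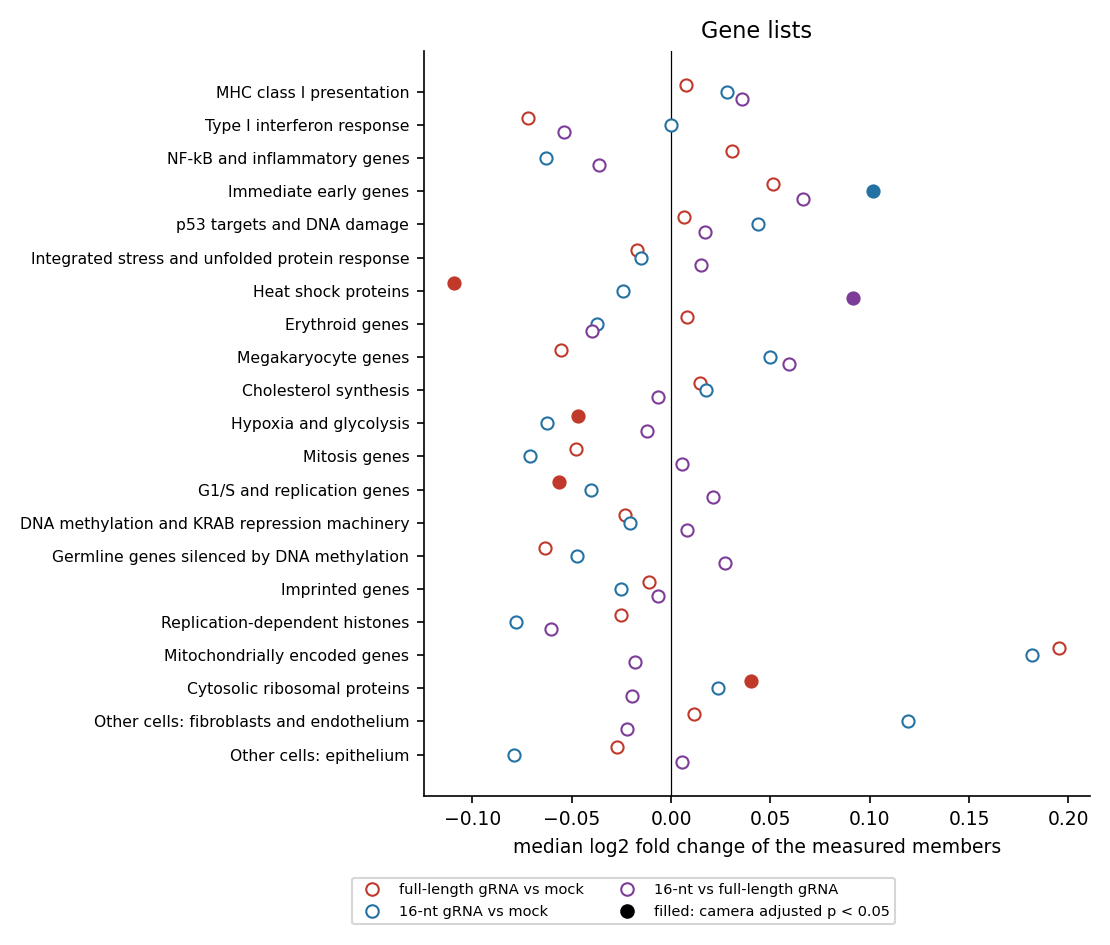
Median log2 fold change of the measured members of each of the 21 tested gene lists in the 3 comparisons between groups, with filled points for lists called by camera. The called lists are 4 with the full-length gRNA against mock, 1 with the 16-nt gRNA against mock and 1 between the gRNAs, and their medians lie between -0.11 and 0.10.

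The second comparison asked the same of the 16-nt gRNA. B2M fell 7.21-fold against mock (95% CI 6.13 to 8.48), a log2 fold change of -2.85 (SE 0.11, edgeR adjusted p = 1.08e-09). Immediate early genes, transcription factors and phosphatases that cells transcribe within minutes of a stimulus, rose together, with 19 of 20 measured members higher and a median log2 fold change of 0.10. This list had a camera adjusted p = 0.00828, and adjusted p = 0.779 with an estimated correlation. Its adjusted p was 0.494 without both ETR replicate 3 libraries, 0.487 without 16-nt gRNA replicate 3 and 0.128 without mock replicate 1. FOSL1, an AP-1 subunit, went from 7.01 ± 0.395 to 9.12 ± 2.12 CPM (SD, n = 3 each), a log2 fold change of 0.38 (SE 0.17). DUSP5, FOS and ZFP36, which encode a MAP kinase phosphatase, an AP-1 subunit and an mRNA decay factor, had log2 fold changes of 0.31, 0.21 and 0.26. Without 16-nt gRNA replicate 3, FOSL1 stood at 0.17 and FOS at 0.068. ZFP36 stood at 0.13 without mock replicate 1 and 0.48 without mock replicate 2, where FOS stood at 0.11.

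B2M was again the only gene called, by edgeR and by DESeq2, with 0 genes that rose and 1 that fell. At an unadjusted p under 0.05 edgeR gave 377 genes, or 2.48%, again under the 5% that chance alone would give, and DESeq2 gave 308. The next lowest edgeR adjusted p was 0.978. Without a filter on low counts 13 genes were called. The 95% confidence interval lay within 2-fold for 98.9% and within 1.5-fold for 90.7% of the 11704 genes with a mean log2 CPM of at least 1. SCNN1D again had the largest positive log2 fold change among these, 0.95 (SE 0.38).

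The other 20 tested lists were not called with the 16-nt gRNA (camera adjusted p from 0.0590 to 0.835). Some were called with 1 library left out. Without mock replicate 3 histones were lower (camera adjusted p = 5.86e-09), as were erythroid genes (3.07e-05). Without mock replicate 2 mitochondrially encoded genes were higher (1.40e-05). The heat shock list had 6 of 18 members higher (HSPA4L, log2 fold change -0.15), hypoxia and glycolysis 8 of 31 (NDRG1, -0.21), G1/S and replication 10 of 28 (cyclin E2 gene CCNE2, -0.36) and mitosis 5 of 24 (the checkpoint kinase TTK, -0.16). MHC class I presentation genes had 11 of 18 higher (HLA-C, 0.14), interferon genes 10 of 20 (IFI27, -0.37) and NF-kB genes 5 of 15 (CD83, -0.38). p53 targets had 14 of 23 higher (PLK3, 0.31) and the integrated stress list 13 of 30 (VLDLR, -0.34). Erythroid genes had 11 of 34 higher (TFRC, -0.27), megakaryocyte genes 4 of 6 (CD9, -0.26) and cholesterol synthesis genes 17 of 25. Of the repression machinery 10 of 24 were higher (ZBTB38, which encodes a methyl-CpG binding protein, -0.25), of germline genes 7 of 18 (CTAG2, 0.16), of imprinted genes 6 of 16 (MEST, -0.22) and of histones 3 of 22 (H2AC17, -0.46, uncertain for its near-identical copies). TFRC and H2AC17 stood at -0.16 and -0.10 without mock replicate 1, and IFI27, CD9, ZBTB38 and H2AC17 at -0.16, -0.17, -0.14 and -0.75 without mock replicate 3. IFI27, CD83 and CD9 stood at -0.24, -0.078 and -0.15 without 16-nt gRNA replicate 1, and CD83 at -0.61 without 16-nt gRNA replicate 3.

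Mitochondrially encoded genes had 11 of 13 members higher with the 16-nt gRNA (MT-ND6, log2 fold change 0.25, but -0.044 without mock replicate 1) and ribosomal proteins 47 of 74 (RPL36, 0.19, uncertain for its pseudogenes). Fibroblast and endothelial genes had 5 of 7 higher (FN1, -0.15) and epithelial genes 3 of 10 (CLDN3, -0.41). Of genes of other blood cells, 2 of 2 lymphocyte genes were higher, as were 2 of 3 of monocytes and granulocytes (CSF3R, 0.89, SE 0.43). MT-ND6 and RPL36 stood at 0.47 and 0.33 without mock replicate 2, and MT-ND6 and RPL36 at 0.38 and 0.11 without mock replicate 3. MT-ND6 and FN1 stood at 0.40 and -0.073 without 16-nt gRNA replicate 1, and MT-ND6 at 0.14 without 16-nt gRNA replicate 2. RPL36 and FN1 stood at 0.096 and -0.23 without 16-nt gRNA replicate 3. Over all lists edgeR called 0 of 478 members and DESeq2 0, with 9 and 10 at an unadjusted p under 0.05, and adjusted over the list alone 0 were called in each list. Median and test differed in sign for megakaryocyte genes.

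The third comparison asked whether shortening the gRNA changed the response. B2M was 1.98-fold higher with the 16-nt than with the full-length gRNA (95% CI 1.67 to 2.35), a log2 fold change of 0.99 (SE 0.12, edgeR adjusted p = 0.00580). Each 16-nt gRNA library lay above each full-length gRNA library. The heat shock list rose, with 14 of 18 measured members higher and a median log2 fold change of 0.091. It had a camera adjusted p = 0.00752, and adjusted p = 0.422 with an estimated correlation. Its adjusted p was 0.0444 without both ETR replicate 3 libraries and 0.142 without full-length gRNA replicate 3 alone. HSPE1 and HSPD1, partner genes of the mitochondrial HSP60 chaperonin, had log2 fold changes of 0.18 each (SE 0.11 and 0.12). HSPA1A and HSPA1B, near-identical HSP70 genes whose split of reads is uncertain, had 0.28 and 0.20. Without 16-nt gRNA replicate 1, HSPD1 stood at 0.031, HSPA1A at 0.43 and HSPA1B at 0.33. Without full-length gRNA replicate 3, HSPA1A and HSPA1B stood at 0.43 and 0.38, and HSPA1B stood at 0.089 without full-length gRNA replicate 1 and 0.083 without 16-nt gRNA replicate 3.

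B2M was the only gene called between the gRNAs by edgeR and by DESeq2, with 1 gene that rose and 0 that fell. At an unadjusted p under 0.05 edgeR gave 141 genes, or 0.927%, and DESeq2 gave 94, while 4 genes were called without a filter on low counts. Chance alone would give 5%, and this fit left out the pairing of these groups by replicate number. With the replicate number as a block edgeR gave 242 genes. The single call therefore does not show that few other genes differed. The 95% confidence interval lay within 2-fold for 99.6% and within 1.5-fold for 93.1% of the 11704 genes with a mean log2 CPM of at least 1. The B2M call was lost without full-length gRNA replicate 2 (log2 fold change 0.95, edgeR adjusted p = 0.12) and in a fit of these 6 libraries alone (0.99, edgeR adjusted p = 0.13). Over all its alternatives the adjusted p ranged from 3.88e-14 to 0.13.

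The other 20 tested lists were not called between the gRNAs (camera adjusted p from 0.156 to 0.870). HBE1, the embryonic epsilon globin gene, had the largest negative log2 fold change among genes with a mean log2 CPM of at least 1, -0.70 (SE 0.21). Its level was 5.48 ± 0.776 CPM with the 16-nt gRNA, 8.88 ± 2.04 CPM with the full-length gRNA and 6.90 ± 2.09 CPM in mock cells (SD, n = 3 each). Of erythroid genes 12 of 34 were higher with the 16-nt gRNA (camera adjusted p = 0.216, and 0.954 with an estimated correlation). Without both ETR replicate 3 libraries the erythroid list was called as lower (camera adjusted p = 0.0132). Other lists were also called with 1 library left out. Mitochondrially encoded genes were higher without full-length gRNA replicate 2 (camera adjusted p = 7.01e-07) and lower without full-length gRNA replicate 1 (0.00367). Megakaryocyte genes had 3 of 6 higher (RUNX1, 0.21), immediate early genes 17 of 20 (FOSL1, 0.24), NF-kB genes 6 of 15 (NFKBIA, -0.19), interferon genes 8 of 20 (BST2, 0.14) and MHC class I genes 10 of 18 (CANX, 0.16). p53 targets had 13 of 23 higher (DDB2, -0.14), the integrated stress list 17 of 30 (HERPUD1, -0.14), cholesterol synthesis 12 of 25 (PMVK, 0.22), hypoxia and glycolysis 14 of 31 (ALDOA, 0.22), mitosis 13 of 24 (CENPF, 0.11) and G1/S and replication 18 of 28 (GINS1, 0.14). FOSL1 and RUNX1 stood at 0.11 and 0.11 without full-length gRNA replicate 1, and CANX at 0.080 without full-length gRNA replicate 2. FOSL1, PMVK and CENPF stood at 0.39, 0.35 and 0.068 without full-length gRNA replicate 3, and CANX, PMVK and ALDOA at 0.071, 0.10 and 0.10 without 16-nt gRNA replicate 1. CENPF stood at 0.070 without 16-nt gRNA replicate 2, and FOSL1 at 0.037 without 16-nt gRNA replicate 3.

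The repression machinery had 14 of 24 members higher with the 16-nt than with the full-length gRNA (ZBTB38, log2 fold change -0.27), germline genes 10 of 18 (MAGEA12, -0.12), imprinted genes 7 of 16 (PLAGL1, -0.30), histones 7 of 22 (H4C5, 0.33, uncertain as above), mitochondrially encoded genes 5 of 13 (MT-CO1, -0.25) and ribosomal proteins 34 of 74 (RPL29, -0.22, uncertain as above). Fibroblast and endothelial genes had 3 of 7 higher (FN1, -0.075, but 0.018 without full-length gRNA replicate 3 and 0.0060 without 16-nt gRNA replicate 1) and epithelial genes 5 of 10 (ESRP1, -0.34). Lymphocyte genes had 1 of 2 higher (CD3D, -0.77) and monocyte and granulocyte genes 3 of 3 (CSF3R, 0.17, SE 0.40, but -0.0052 without full-length gRNA replicate 1). MT-CO1, FN1 and ESRP1 stood at -0.025, -0.17 and -0.22 without full-length gRNA replicate 2, and MT-CO1, CSF3R and ESRP1 at -0.41, 0.34 and -0.53 without full-length gRNA replicate 3. MAGEA12, H4C5, CSF3R and ESRP1 stood at -0.063, 0.15, 0.050 and -0.16 without 16-nt gRNA replicate 1, and CSF3R at 0.37 without 16-nt gRNA replicate 2. CSF3R and FN1 stood at 0.094 and -0.15 without 16-nt gRNA replicate 3. Over all lists edgeR called 0 of 478 members and DESeq2 0, with 3 and 4 at an unadjusted p under 0.05. Adjusted over the list alone 0 were called in each list. Median, mean and test differed in sign for cholesterol synthesis, hypoxia and glycolysis, mitosis, mitochondrially encoded and epithelial genes.

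Genes around B2M were examined because a repressor placed at a promoter can act on its neighbours. Of 82 annotated genes within 1 Mb, 22 were measured, and edgeR and DESeq2 called 0 of them in any of the 3 comparisons between groups. At an unadjusted p under 0.05 edgeR gave 4 with the full-length gRNA, 2 with the 16-nt gRNA and 0 between the gRNAs, as did DESeq2. Over all tested genes the edgeR shares were 2.86%, 2.48% and 0.927%. Of the 4 neighbours 3 were higher, and of the 2 neighbours 2 were. TRIM69, 10.1 kb from B2M, and EIF3J, chosen here after their values were seen, had 0.33 (SE 0.12) and -0.26 (SE 0.11) with the full-length gRNA. Adjusted over the list alone 0 passed, with lowest adjusted p values of 0.0974, 0.193 and 0.956. Of the 17 neighbours with a mean log2 CPM of at least 1, 16 had a 95% confidence interval within 2-fold in each comparison. PATL2, on the minus strand from 44665732 to 44711316 and separated from B2M by 170 bp, had log2 fold changes of 2.20 (SE 0.73) with the full-length gRNA and 1.93 (SE 0.75) with the 16-nt gRNA. Its counts were 3, 0 and 7 in mock libraries, 8, 12 and 25 with the full-length gRNA and 10, 10 and 18 with the 16-nt gRNA. Without mock replicate 3 these fold changes were 3.30 and 3.03, and without mock replicate 2 that with the 16-nt gRNA was 1.28. With the first principal component as a covariate, its value for the 6 ETR libraries together went from 2.07 (SE 0.65) to 1.39 (SE 0.58). CATSPER2P1, a pseudogene near the far end of this window, had 0.67 and 0.64 (SE 0.21 each) and is uncertain because it shares sequence with its parent gene. Between the gRNAs, the translation initiation gene EIF3J had 0.16 (SE 0.11) and SERF2 0.23 (SE 0.17). Without full-length gRNA replicate 1 these were 0.26 and 0.067, and without full-length gRNA replicate 3 they were 0.098 and 0.41. EIF3J stood at 0.11 without 16-nt gRNA replicate 1 and 0.25 without 16-nt gRNA replicate 3.

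**Figure D4:**
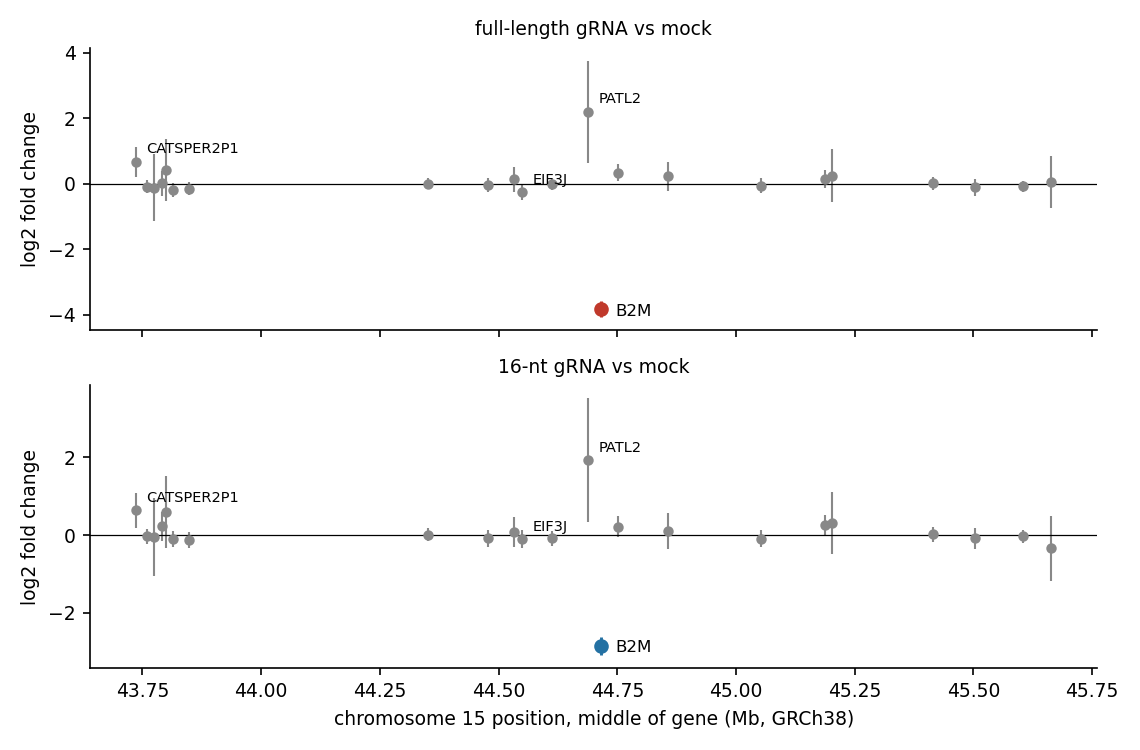
Log2 fold change against mock of the measured genes within 1 Mb of B2M on chromosome 15, by position, for the full-length and the 16-nt gRNA, with bars for the 95% confidence interval. B2M lies at -3.84 and -2.85, and PATL2, with at most 25 counts in a library, at 2.20 and 1.93.

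Both ETR groups were set against the same mock libraries. B2M was called in both comparisons, and 0 genes were called with one gRNA alone by edgeR or DESeq2. In 20 simulations of unchanged groups against shared controls, 0.10 genes on average and at most 1 were called in both. Independent lists would share 6.57e-05 falling genes. Both gRNAs were directed at B2M, so its overlap followed from the design, and these chance values do not bear on a shared response. Across 11703 genes other than B2M, which are not independent replicates, the fold changes against mock correlated at r = 0.716. The simulated shared controls gave 0.496 (range 0.481 to 0.515). The covariance was 0.0132 against a simulated 0.00986, a difference of 0.00332, and 76.3% of genes shared their sign against a simulated 66.6%. The simulated counts were drawn gene by gene, without the variation that genes of a real library share, so the simulated range may be too narrow. The 3 mock libraries cannot be split into parts of 2, so part or all of the excess may come from the shared controls. ETR libraries with the same replicate number also deviated together.

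With the 6 ETR libraries taken as 1 group against the 3 mock libraries, B2M fell 9.58-fold (95% CI 7.10 to 12.9), a log2 fold change of -3.26 (SE 0.20, edgeR adjusted p = 5.06e-07). This value averages 2 gRNA groups that differed 1.98-fold in B2M. Its SE and interval therefore include that difference as well as the spread between libraries. An exact two-sided permutation test of log2 CPM gave p = 0.0238, the smallest that 6 against 3 libraries allow. B2M was the only gene called by edgeR and by DESeq2, with 653 and 675 genes at an unadjusted p under 0.05 and a next lowest edgeR adjusted p of 0.143. Without a filter on low counts 30 genes were called. Of the neighbours of B2M, 1 passed when adjusted over the list alone, CATSPER2P1 (log2 fold change 0.65, SE 0.18, edgeR adjusted p = 0.0437 over that list and 0.885 over all genes).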

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

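The fits without both ETR replicate 3 libraries, and gene lists scaled by library totals alone, were chosen only after the results were seen. B2M kept its direction under every alternative run. Leaving out 1 library in turn, its log2 fold change ranged from -3.92 to -3.79 with the full-length gRNA, from -2.98 to -2.75 with the 16-nt gRNA, from 0.86 to 1.09 between the gRNAs and from -3.44 to -3.16 for either gRNA, and 1 gene was called in each case except between the gRNAs, where 0 to 1 were. Between the gRNAs, 0 genes were called without full-length gRNA replicate 2 (B2M 0.95) and in a fit of the 2 groups alone (B2M 0.99, edgeR adjusted p = 0.13). Fewer libraries alone do not account for the first loss. Without both ETR replicate 3 libraries B2M was still called between the gRNAs (1.05, edgeR adjusted p = 0.0118). With an absolute log2 fold change of at least 1 required 0 genes were called, since 0.99 lies under it. Without a filter on low counts 6 genes were called with the full-length gRNA (2 higher, 4 lower), 13 with the 16-nt gRNA (8 and 5), 4 between the gRNAs (4 and 0), 30 for either gRNA (21 and 9) and 4 in both ETR comparisons. That fit gave every gene the spread of the trend (infinite prior degrees of freedom against 8.98), which took the SE of MT-RNR1, chosen after its values were seen, with 58 to 1066 counts per library, from 0.727 to 0.133. Called gene lists numbered 4, 1 and 1 for full-length against mock, 16-nt against mock and between the gRNAs. They numbered 0, 0 and 0 with an estimated correlation, 0, 0 and 0 with fry, 1, 0 and 2 without both ETR replicate 3 libraries, and 1 to 7, 0 to 7 and 1 to 6 with 1 library left out; with library totals alone 2 were called for 16-nt against mock. The cause was not tested. With the replicate block 5 lists were called in each comparison with mock, and it changed no other call. It added mitochondrially encoded genes as higher with the full-length gRNA (camera adjusted p = 0.0106) and with the 16-nt gRNA (0.000316). With the 16-nt gRNA it also added hypoxia and glycolysis (0.0235), mitosis (0.0424) and histone genes (0.0235) as lower. At an unadjusted p under 0.05 the block gave 886, 921, 242 and 1339 genes with the full-length gRNA, with the 16-nt gRNA, between the gRNAs and for either gRNA, against 435, 377, 141 and 653 without it. Deviations from the group means correlated at 0.199, 0.0334 and 0.209 between full-length gRNA and mock libraries with the same number and at 0.0606, -0.191 and 0.197 between 16-nt gRNA and mock libraries. In these, 6 of 6 and 3 of 6 libraries correlated best with their own number, a hint from the data and not from the design. Of 97 named gene results under 1626 alternatives, 1615 kept their call and direction. None of the 97 was called in the main fit, so keeping the call meant staying uncalled and says little about stability. Leaving out 1 library moved 59 of the 97 values by over 1.5 times. With 1 library left out, sign changed for MT-CO1 with the full-length gRNA (-0.033 to 0.36, negative without full-length gRNA replicate 2). With the 16-nt gRNA it changed for MT-ND6 (-0.044 to 0.47, negative without mock replicate 1). Between the gRNAs it changed for CSF3R (-0.0052 to 0.37, negative without full-length gRNA replicate 1) and FN1 (-0.17 to 0.018, positive without full-length gRNA replicate 3 and, at 0.0060, without 16-nt gRNA replicate 1). The cause was not tested. FIRRE, PREX2, RELN, SCNN1D, MAPK8IP3 and DDX39B, also chosen after their values were seen, passed for either gRNA only without the filter. Depth limits low genes such as PATL2, with 0 to 25 counts per library.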

Other observations

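The tests of sequencing depth and of a step shared by replicate numbers were chosen only after the result was seen, and the genes and libraries below were picked for their values. FIRRE, a long noncoding RNA that acts in nuclear architecture, had 23, 29 and 18 counts in mock libraries, 4, 7 and 2 with the full-length gRNA and 8, 2 and 4 with the 16-nt gRNA, a log2 fold change of -2.29 for either gRNA (SE 0.38, edgeR adjusted p = 0.143). PREX2, an exchange factor for Rac, and RELN, which encodes the extracellular protein reelin, had -1.49 and -1.47 (SE 0.31 and 0.30, edgeR adjusted p = 0.685 each). All 6 ETR libraries lay below all 3 mock libraries for these 3 genes, and none passed in the edgeR test with the low-count filter as set or in the DESeq2 test of all 33525 genes with a count.

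FIRRE, PREX2 and RELN lay lower in every ETR library, and a candidate explanation is the main axis of variation between libraries. With the first principal component as a covariate their median log2 fold change was -1.38 (median SE 0.332), against -1.49 without it. The genes were picked because they part ETR from mock libraries, which this axis does not. The test therefore cannot decide whether the axis contributed. Separation by chance among many low genes stays open: 40 low genes had all 6 ETR libraries below all 3 mock libraries, and 23 of the 84 splits of the 9 libraries gave as many, with a highest other of 261. An effect of the ETR or gRNA away from B2M also stays open as a hypothesis and was not tested.

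PATL2, beside B2M, had more counts in each ETR library than in each mock library, a log2 fold change of 2.07 for either gRNA (SE 0.65, edgeR adjusted p = 0.885) that was 3.17 without mock replicate 3. With the first principal component as a covariate the value was 1.39 (SE 0.58), so the main axis of library variation and a change tied to the ETR cannot be told apart at 0 to 25 counts per library. An effect of the ETR on transcription that starts at the B2M promoter may be considered as a hypothesis, which needs strand-resolved reads and was not tested.

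Both ETR replicate 3 libraries lay at one end of the first principal component, and no biological explanation was tested. With all 9 libraries thinned at random to the lowest total, the gap to the nearest other library was 40.3% of the range of this axis (SD 0.555 over 20 thinnings), against 40.7% at full depth, which argues against depth. Gene length is argued against by explaining 5.08% (bootstrap SD 0.484) of the variance of their difference over genes, while GC content explained 12.97% (bootstrap SD 0.571), which leaves it open as a part. A candidate explanation is more unspliced or nuclear RNA: the median difference of 118 sense intronic transcripts was 0.35 against 0.19 in sets matched on expression, the percentile 99.87 of 10000 such sets. The sets were not matched on GC content and drew genes independently, though genes of a library vary together. The percentile therefore does not set this explanation above GC content. A step shared by libraries with the same replicate number cannot be told apart from other causes. Replicates 1, 2 and 3 came in this order on the axis in all 3 groups. An exact permutation test of these ranks gave p = 0.0278, the smallest that the 216 permutations within groups allow. The lowest same-number correlation was however -0.191, between 16-nt gRNA and mock replicate 2.

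Other splits of the samples gave the following counts. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. With the full-length gRNA 2 of 10 gave at least the real 1 gene (highest other 3) and 6 at least the real 4 lists (highest other 10). With the 16-nt gRNA 2 of 10 gave at least 1 gene (highest other 31) and 10 at least 1 list (highest other 8). Between the gRNAs 3 of 10 gave at least 1 gene (highest other 9) and 10 at least 1 list (highest other 9). Of the 4 splits that part all 3 replicate pairs, the real one called 1 gene and the others 0, while splits that keep a pair together called up to 9. For either gRNA, 8 of the 84 splits gave at least the real 1 gene, so chance is not excluded for that count. Of the 10 splits that keep each ETR pair of 1 replicate number together, as the real one does, 3 gave at least 1 gene (highest other 2). All 7 other splits with a gene set 2 or 3 libraries of 1 number apart, and the other 26 splits that set 1 library of each number apart called 0 genes. Whether the numbers also pair the mock libraries with the ETR libraries is not settled. The replicate numbers came in the same order on the first principal component in all 3 groups. Of the full-length gRNA and mock libraries, 6 of 6 correlated best with their own number. Of the 16-nt gRNA and mock libraries 3 of 6 did, and their replicate 2 libraries correlated at -0.191. The highest other was 340 genes, for a split that sets both ETR replicate 3 libraries and another ETR library apart, which points to a structure of the samples.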
